A study of Mus musculus with 6 samples.

How the data were processed

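Total RNA from Müllerian ducts of 6 mouse embryos was hybridised to Affymetrix whole-transcript arrays, 1 array per embryo, and the labels call the 3 samples of each genotype biological replicates. The authors deposited 1 table of log2 signals, with a column per array. Transcriptome Analysis Console 4.0 was used, per the submitters' processing notes. The method that summarised probes and normalized the arrays is not given in the sources used here. The deposited log2 values ran over nearly the same quantiles on every array, with medians between 6.87 and 6.95, and were used without further normalization. Detection calls were not analysed here.

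The table held 28846 rows. The 22206 transcript clusters were tested. Control rows were left out of the tests: 5222 negative and 1324 positive controls, 63 ERCC spikes, 8 hybridisation or poly-A spikes and 23 antigenomic background probes. The median of the background probes of each array, from 5.35 to 5.88, served as its background level, and a gene below it on every array of a group is described as below background, and the size of a change from or to such a signal is of little precision. The negative-control rows had higher medians, from 7.09 to 7.41, and did not set this level. Gene symbols came from the platform's probe table, in which 19572 tested rows had 1 symbol, 0 had several and 2634 were not listed. There were 19505 different symbols, 55 of them on more than 1 row, and 254 rows had the same 6 values as another row. Rora was among the genes whose rows disagreed, with a row that rose and another that fell. No genome build was given, so no coordinates are reported.

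Groups were taken from the genotype in the labels. Each transcript cluster was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with genotype as the only term, the default prior and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all tested rows, and 0.05 was the threshold. Changes of at least 2-fold were counted besides. Gene lists were tested with camera of limma at a preset correlation of 0.01, with 1 row per gene (the row with the highest mean over all arrays), adjusted over 30 lists. The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. Member counts were also adjusted over the list alone.

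The text names Lats1, Lats2, Amhr2, Yap1 and Wwtr1, the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between groups, and up to 4 members of each list with the smallest p. Predicted and unnamed genes were left out of the largest changes, and a list that moved both ways could have its 2 smallest p of each direction named. A gene outside this rule is said to have been named after its value was seen. Fold changes are log2 differences of group means with limma standard errors, and the median standard error was 0.197. The smallest change that passed the threshold was 0.69.

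The fit was tested on simulated data of 22206 rows with 200 changed rows. Of those changed by 1 on the log2 scale 47% were recovered, and of those changed by 2, 84%. All recovered rows had the right sign, and 3 unchanged rows were called.

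Alternatives were quantile normalization, arrays shifted to a common median, filters on rows under the 25th percentile or the median of mean signal, a trended and robust prior, array weights, the replicate number as a block, rows with 1 symbol only, a threshold of 0.01, a plain unequal-spread test per row, and each array left out in turn. For the lists, camera with an estimated correlation, fry and the mean of a gene's rows were also run. Fry tests a list for a change of its own, whereas camera sets it against other genes. Lists of 6 further groups, 2 lists of urothelial markers and the member counts with 1 array left out were added after seeing the data. Intervals are at 95%, by limma's moderated spread or by 10000 bootstrap resamples over genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.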

Results

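Gene expression was measured in Müllerian ducts of mouse embryos at E17.5, a late embryonic stage, with 1 array for each of 6 embryos. The Müllerian duct is the embryonic tube from which the oviducts, uterus and upper vagina form. Its mesenchyme expresses Amhr2, the receptor of anti-Müllerian hormone. The 3 control embryos carried floxed alleles of Lats1 and Lats2, which encode the kinases that restrain the coactivators YAP and TAZ in the Hippo pathway. The 3 mutant embryos carried the same alleles and Cre recombinase in the Amhr2 locus. The deposited table gave a log2 signal for 22206 transcript clusters on each Affymetrix array, of which 19572 had a gene symbol. Array medians lay between 6.87 and 6.95, and the background probes of each array had medians between 5.35 and 5.88. The number of arrays limits the precision, and all comparisons are of 3 mutant with 3 control arrays.

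The targeted genes were read first. Lats1 had a mean log2 signal of 12.28 ± 0.20 (SD, n = 3) in control and 11.50 ± 0.34 (SD, n = 3) in mutant ducts, a log2 fold change of -0.78 ± 0.21 (SE) with a limma adjusted p of 0.0958. That difference did not pass the threshold of 0.05, and its 95% interval ran from -1.26 to -0.31. It did pass when rows under the median signal were left out (adjusted p = 0.0453) and with a variance prior that followed the mean signal (adjusted p = 0.0359). Lats2 was at 11.41 ± 0.22 in control and 11.64 ± 0.32 in mutant ducts, with an interval of the log2 fold change from -0.25 to 0.69. Where the array's probes lie relative to the floxed exons is not given in the sources used here, so these values do not check the deletion. Amhr2, whose locus carries Cre in the mutants, fell 13.3-fold from 10.73 ± 0.20 (SD, n = 3), a log2 fold change of -3.73 ± 0.25 (SE) with a limma adjusted p of 0.000112. Wwtr1, which encodes TAZ, rose by 0.99 ± 0.20 (adjusted p = 0.0288), and Yap1 had a log2 fold change of -0.25 ± 0.18 (adjusted p = 0.578). The Wwtr1 call was lost without control 1, control 3, mutant 1 or mutant 3, with adjusted p between 0.0532 and 0.114.

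**Figure D1:**
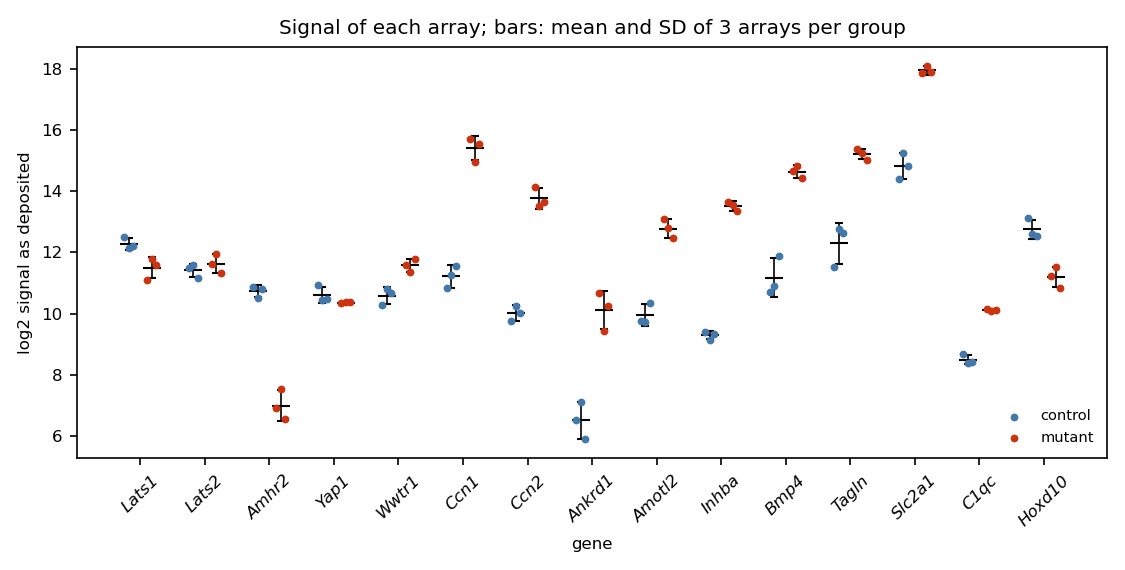
The log2 signal of 15 genes is plotted for each array, control arrays in blue and mutant arrays in red, with the mean and SD of 3 arrays per group as bars. The 3 mutant arrays lie below all control arrays for Amhr2 and above them for Ccn1, Ccn2, Inhba and Bmp4.

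The comparison of mutant with control ducts asks how expression differs between the genotypes, which differ in Cre at the Amhr2 locus as well as in the alleles it acts on. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, had the largest rise among the named genes, 138.1-fold, from 5.59 ± 0.64 to 12.70 ± 0.32 (SD, n = 3 each). It was followed by Tac2, a tachykinin precursor, with a log2 fold change of 5.58 ± 0.35 (SE), and by the serine protease inhibitor Serpinb7 with 5.08 ± 0.33. The control signal of Serpinb7 was below background on every array, that of Tac2 on 2 of 3 (control 2 and control 3) and that of Ptgs2 in control 3, and on the other arrays Tac2 and Ptgs2 lay within 0.82 of it, so these folds and their order are of little precision. The glucose transporter Slc2a3 rose by 4.51 ± 0.21, and Inhba, the activin beta A subunit, by 4.22 ± 0.17. Rcan2, Tnfrsf12a, Osmr, Bhlhe40 and Gadd45g each rose by between 3.75 and 3.97. Of the falls, Amhr2 was the largest measured above background. Retnlg was at -2.92 ± 0.22, the glutamate receptor subunit Gria1 at -2.83 ± 0.22 and the actin-binding protein Synpo2 at -2.64 ± 0.33. The axon guidance receptor Robo2 fell by 2.46, the mineralocorticoid receptor Nr3c2 by 2.16 and the cannabinoid receptor Cnr1 by 2.07. Sptlc3 fell by 2.30, and its mutant signal, like that of Retnlg, was below background on every array, so the size and order of these falls are of little precision. The falls of Gstm7 (-2.53), Slc14a1 (-2.50), Stfa2 (-2.34) and Stfa2l1 (-2.08) passed the threshold but were each lost in 3 or 4 of the 6 fits that left out 1 array, with adjusted p up to 0.145.

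Across all 22206 transcript clusters, 723 passed an adjusted p of 0.05, of which 575 rose and 148 fell. At least 2-fold changes numbered 548, with 448 rises and 100 falls, and none of these overlapped between groups. Over all transcript clusters, 21.1% did not overlap between groups, where chance gives 10% for 3 against 3. Genotype followed the first principal component, which took 42.4% of the variance. Correlations between arrays ranged from 0.9887 to 0.9928 within a group and from 0.9836 to 0.9868 between groups. The second component, with 19.6%, set control 3 (score -42.62) apart from control 1 (16.25) and control 2 (28.8). The total fell to 384 without control 1, 454 without control 2 and 360 without mutant 1, and was 697 without control 3. Falls then numbered 64, 76, 55 and 132, and 92 without mutant 3, rises were 320, 378 and 305 without control 1, control 2 and mutant 1, and 2-fold changes were 354 without mutant 1.

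**Figure D2:**
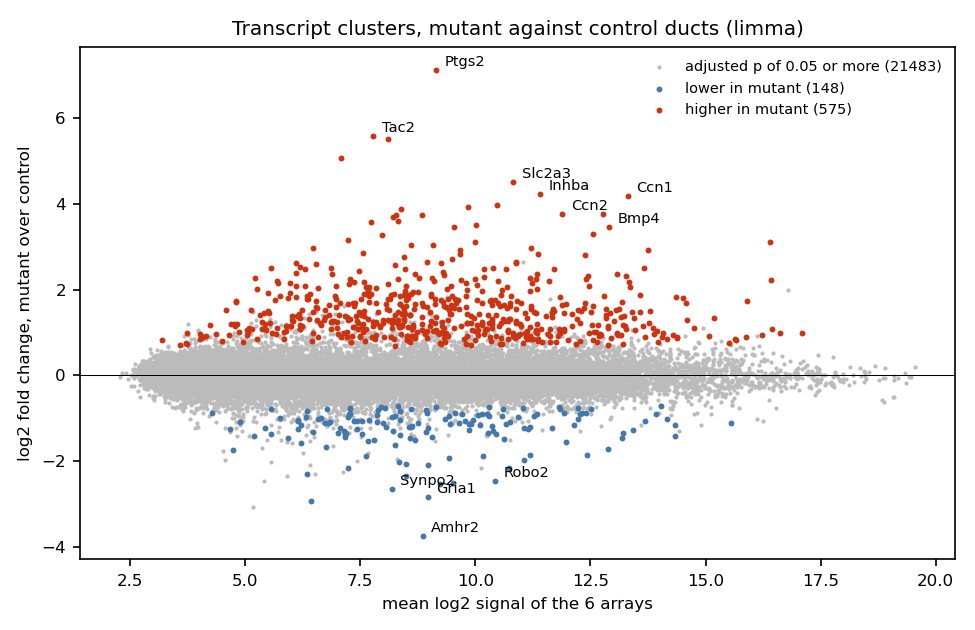
Each of the 22206 transcript clusters is a point, with the mean log2 signal of the 6 arrays on the horizontal axis and the log2 fold change of mutant over control on the vertical axis. Red points are the 575 that rose and blue points the 148 that fell at a limma adjusted p under 0.05.

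Target genes of YAP and TAZ were higher in mutant ducts. Of 22 measured, 12 rose and none fell, or 15 and none when adjusted over the list alone, and their median log2 fold change was 1.21. Ccn1 and Ccn2, matricellular proteins, rose 18.2-fold and 13.5-fold, with log2 fold changes of 4.18 ± 0.26 and 3.76 ± 0.22. Amotl2, a YAP-binding scaffold, rose by 2.83 ± 0.23 and Crim1 by 2.31 ± 0.17. The list stood above other genes in limma's camera test (adjusted p = 3.17e-19), and it was the only list of the 30 called with an estimated correlation (adjusted p = 0.0170). The immediate early and stress list, fixed as a sign of sample quality, moved with these targets. Its mean deviation was between -0.75 and -0.19 on control and between 0.52 and 0.59 on mutant arrays, beside -0.76 to -0.66 and 0.65 to 0.82 for the targets. Among 19 Hippo pathway components, 3 rose and none fell. These were Vgll3, a TEAD cofactor, with 3.50 ± 0.26, Wwc2 with 1.44 ± 0.18, and Wwtr1. Adjusted over the list alone, 5 rose. The components had a median of 0.22 and a camera adjusted p of 0.000234 (adjusted p = 0.127 with an estimated correlation), and the median was 0.37 without mutant 2.

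**Figure D3:**
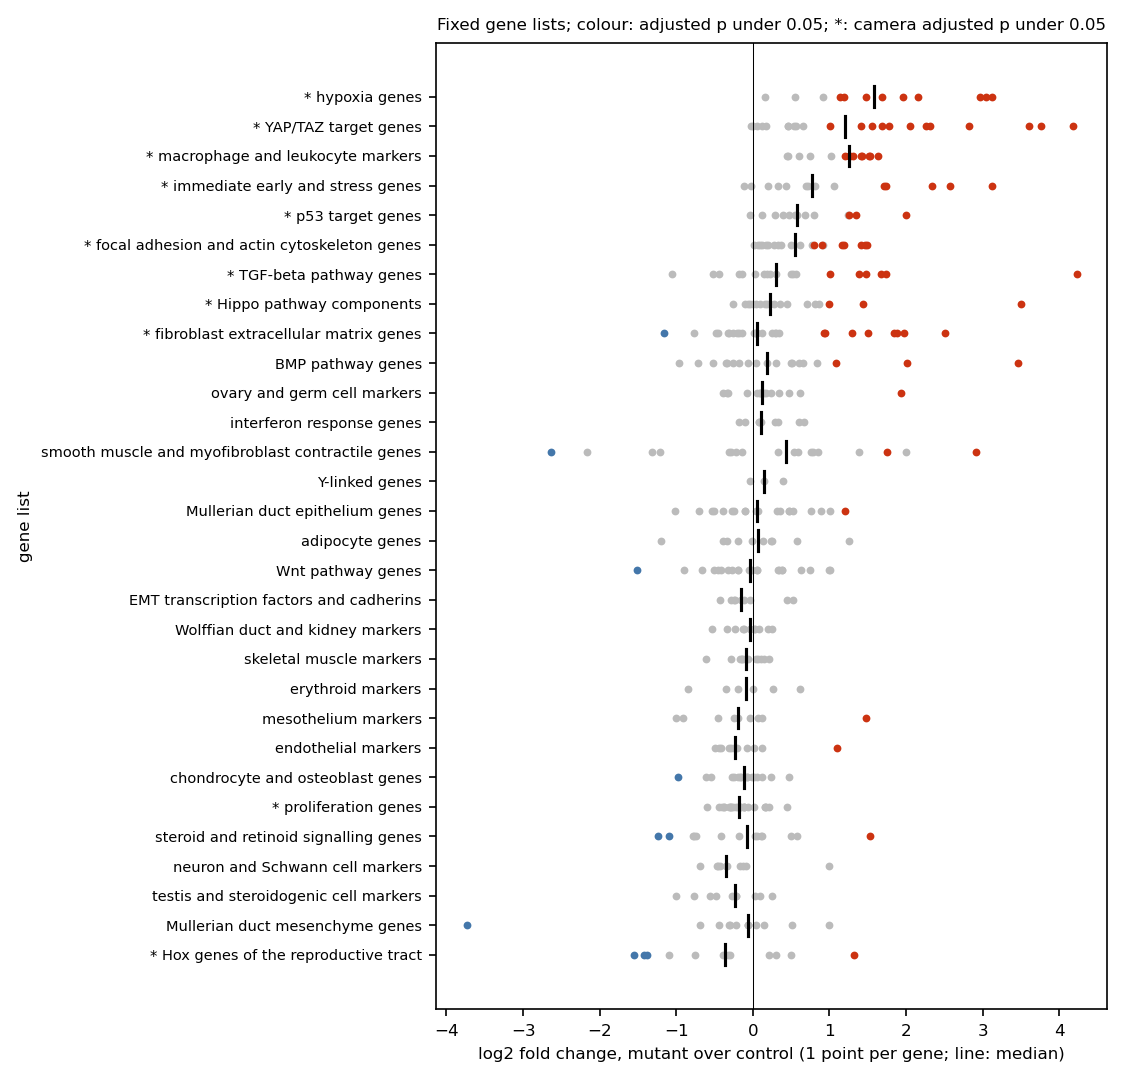
Each point is the log2 fold change, mutant over control, of a gene in 1 of the 30 gene lists, coloured where its adjusted p is under 0.05, and the black lines are list medians. Stars mark the 11 lists with a camera adjusted p under 0.05, among them hypoxia genes (median 1.58) and YAP/TAZ target genes (median 1.21).

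Hypoxia-responsive genes rose in 9 of 12 cases, or 11 of 12 adjusted over the list alone, with none falling and a median of 1.58 (camera adjusted p = 4.74e-15; adjusted p = 0.101 with an estimated correlation). The glucose transporter Slc2a1 rose 8.68-fold from an already high 14.83 ± 0.43 to 17.95 ± 0.13. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 2.97 ± 0.23, Ndrg1 by 2.16 ± 0.25 and the collagen prolyl hydroxylase subunit P4ha1 by 1.48 ± 0.22. Immediate early and stress genes, a list fixed as a sign of sample quality because handling of tissue can induce them, moved with the same groups. They rose in 5 of 14 cases with none falling, or 9 adjusted over the list alone, with a median of 0.77 (camera adjusted p = 1.21e-07; adjusted p = 0.147 with an estimated correlation). Ier3 rose by 3.12 ± 0.27, Fos by 1.71 ± 0.24, and the heat shock genes Hspa1a and Hspa1b by 2.33 and 2.57. The fifth was Egr1 with 1.73, named after its value was seen. Whether handling or genotype raised these genes was not tested. The mean deviation of this list separated the genotypes, as did those of the hypoxia genes (-1.19 to -0.64 in control, 0.82 to 0.87 in mutant), the macrophage markers (-0.60 to -0.51, 0.48 to 0.70) and the Hippo, focal adhesion, extracellular matrix, TGF-beta, BMP and p53 lists. So did the Hox list, which was called down as a set. The mesenchyme, steroid and retinoid, testis and interferon lists also separated them but, like the BMP list, were not called as sets. Each list that separated the genotypes had an exact permutation p of 0.1, the smallest for 3 against 3, so separation alone tells little. The Hspa1b call was lost without control 1, control 2 or mutant 1 (adjusted p up to 0.0697), and 3 members of the immediate early list rose when control 2 or mutant 1 was left out.

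Of 13 p53 target genes, 3 rose and none fell, or 7 and none adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, rose 4.01-fold, and Ccng1 2.55-fold, while Phlda3 rose from a signal below background, against which no fold is given. Phlda3 was also below background in mutant 3. The list's median was 0.58 (camera adjusted p = 2.38e-06; adjusted p = 0.101 with an estimated correlation). No single member of the 24 proliferation genes passed, over all genes or over the list alone, and Mki67 had a log2 fold change of -0.44 ± 0.16. As a set they lay slightly below other genes, with a median of -0.18 (camera adjusted p = 0.0428; adjusted p = 0.526 with an estimated correlation). That call was lost without control 1 (0.0525), control 3 (0.176) or mutant 3 (0.246), under both filters on dim rows (0.0677 and 0.0891) and with array weights (0.0656). With fry, which does not set a list against other genes, the adjusted p was 0.210. The median of the proliferation genes was -0.10 without control 3, -0.30 without mutant 2 and -0.05 without mutant 3. The Phlda3 call was lost in 4 of the 6 fits that left out 1 array, with adjusted p up to 0.117.

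Focal adhesion and actin cytoskeleton genes rose in 7 of 20 cases, or 11 adjusted over the list alone, and none fell. Non-muscle myosin Myh9 rose by 1.49 ± 0.18, vinculin (Vcl) by 1.47 ± 0.19, lamin A/C (Lmna) by 1.19 ± 0.19 and Cnn2 by 1.16 ± 0.19. The list's median was 0.55 (camera adjusted p = 4.14e-10; adjusted p = 0.0893 with an estimated correlation). The Cnn2 call was lost without control 1 or mutant 1 (adjusted p up to 0.0568), and 3 members rose when either was left out and 4 without control 2.

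Extracellular matrix genes of fibroblasts moved both ways, with 8 rises and 1 fall among 27, or 8 and 2 adjusted over the list alone. Thrombospondin 1 (Thbs1) rose by 2.51 ± 0.21, the fibrillar collagen Col11a1 by 1.97 ± 0.20, Col8a1 by 1.85 ± 0.26 and lysyl oxidase (Lox) by 1.30 ± 0.17. Periostin (Postn) fell by 1.16 ± 0.20, a call lost without control 2 or mutant 1 (adjusted p up to 0.0597). The list's median was 0.05 and its mean 0.37, with a camera adjusted p of 0.0397 (adjusted p = 0.343 with an estimated correlation). That call was lost without control 1 (0.0651), mutant 1 (0.0923) or mutant 3 (0.0597) and without rows under the median signal (0.159), and the median was 0.19 without control 2, 0.01 without mutant 1 and 0.15 without mutant 3.

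Contractile genes of smooth muscle and myofibroblasts were dominated by the spread among controls. Of 18 measured, Tagln (2.92 ± 0.31) and Tpm1 (1.75 ± 0.19) rose and Synpo2 (-2.64 ± 0.33) fell, or 4 rose and 1 fell adjusted over the list alone. The list was not called (median 0.43, camera adjusted p = 0.224), and its median was 0.14 without control 1 and 0.25 without control 2. The following genes were named after their values were seen. In control 3, Myh11 was at 12.58, Actg2 at 15.15 and Cnn1 at 11.74, against 6.70 and 7.61, 7.19 and 11.26, and 5.64 and 7.70 in control 1 and control 2. The urothelial genes Upk2 (12.21), Upk1a (13.14) and Psca (11.90) were also high on that array, against at most 4.16, 8.58 and 5.07 on the other 5. Without control 3, an alternative whose member counts were added after seeing the data, 6 of the 18 rose and 1 fell, and the list was called (camera adjusted p = 0.000898). In that fit Acta2, smooth muscle actin, rose by 2.89 ± 0.42 (adjusted p = 0.00712), and over all 6 arrays it had a log2 fold change of 2.00 ± 0.69 (adjusted p = 0.191).

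Of 19 TGF-beta pathway genes 6 rose and none fell, or 8 rose and 2 fell adjusted over the list alone. Besides Inhba, the transcriptional corepressor Skil rose by 1.67 ± 0.18, Pmepa1 by 1.39 ± 0.16 and the latent TGF-beta binding protein Ltbp2 by 1.74 ± 0.20 from below background. Ltbp2 was also below background in mutant 2 and mutant 3, so the size of its rise is of little precision. The list's median was 0.30 (camera adjusted p = 5.72e-05; adjusted p = 0.0893 with an estimated correlation). Of 19 BMP pathway genes, 3 rose, or 8 rises and 3 falls adjusted over the list alone, and the list was not called (camera adjusted p = 0.0573) except without control 1 (0.0271) or with fry (0.0276). Bmp4 rose by 3.47 ± 0.29, from 11.18 ± 0.63 (SD, n = 3). The BMP antagonist Grem1 rose by 2.01 ± 0.28 from below background, and it was below background in mutant 2 as well. Nog rose by 1.09 ± 0.22, a call lost in 5 of the 6 fits that left out 1 array (adjusted p up to 0.121). In the Wnt pathway list, 1 of 22 genes passed, or 2 rises and 1 fall adjusted over the list alone. Sfrp4, a secreted Wnt inhibitor, fell by 1.51 ± 0.23, and the list had a median of -0.03 (camera adjusted p = 0.932).

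Patterning genes of the Hox family differed between genotypes in 4 of 12 cases. Of these, Hoxd9 (-1.38 ± 0.17), Hoxd10 (-1.56 ± 0.23) and Hoxd11 (-1.42 ± 0.20) fell and Hoxc8 (1.33 ± 0.18) rose, or 5 falls and 1 rise adjusted over the list alone. The list had a median of -0.36 (camera adjusted p = 0.0210; adjusted p = 0.343 with an estimated correlation), and its call was lost without mutant 3 (0.0579), while 5 members fell without mutant 2. With fry, which does not set the list against other genes, its adjusted p was 0.0647. Of 13 mesenchyme genes, Amhr2 passed and fell, and adjusted over the list alone 1 rose and 1 fell. Wnt4 had a log2 fold change of 1.00 ± 0.23 (adjusted p = 0.0530) and Osr2 of -0.69 ± 0.25. The list was not called (median -0.07, camera adjusted p = 0.234). Of 20 epithelial genes Lhx1 passed, over all genes and over the list alone, with 1.20 ± 0.25 at a signal below background in both groups, and it was lost in 5 of the 6 fits that left out 1 array (adjusted p up to 0.120). The epithelial list was not called over all arrays (median 0.05, camera adjusted p = 0.493) but was called up without control 3 (0.0263) and without mutant 3 (0.00230), where 2 members rose. Cdh1, named after its value was seen, stood at 12.34 in control 3, where the urothelial transcripts were high, and at 9.66 and 9.56 in control 1 and control 2. None of 9 genes of the epithelial-mesenchymal transition passed, over all genes or over the list alone (median -0.16, camera adjusted p = 0.613). Of 14 steroid and retinoid signalling genes, the retinoic acid hydroxylase Cyp26a1 rose by 1.53 ± 0.27 from below background. Its signal was also below background in mutant 1 and mutant 2, so the size of that rise is of little precision. The retinoic acid binding proteins Crabp1 and Crabp2 fell by 1.24 ± 0.24 and 1.09 ± 0.22, and adjusted over the list alone 2 rose and 4 fell (median -0.07, camera adjusted p = 0.431). The calls of these 3 genes were lost in 3 or 4 of the 6 fits that left out 1 array, with adjusted p up to 0.112.

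Macrophage markers were higher in mutant ducts. Of 14 measured macrophage and leukocyte markers, 9 rose and none fell, or 12 and none adjusted over the list alone, with a median of 1.26 (camera adjusted p = 2.42e-15; adjusted p = 0.0667 with an estimated correlation). The complement genes C1qa, C1qb and C1qc rose by 1.42 ± 0.18, 1.52 ± 0.16 and 1.63 ± 0.16, and Laptm5 rose by 1.52 ± 0.17. Endothelial markers had 1 rise in 14, over all genes and over the list alone. This was Kdr, the VEGF receptor, with 1.10 ± 0.16, and the list's median was -0.23 (camera adjusted p = 0.175). Mesothelial markers had 1 rise in 9, Msln with 1.48 ± 0.22, or 1 rise and 1 fall adjusted over the list alone (median -0.19, camera adjusted p = 0.462).

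Markers of other tissue that a dissected duct could hold changed little, but many lay below background in both groups, where a change is hard to measure. These were 7 of 11 testis, 7 of 16 chondrocyte and osteoblast, 6 of 13 skeletal muscle and 5 of 11 Wolffian duct and kidney markers. They were also 5 of 10 neuron, 5 of 14 ovary, 3 of 10 adipocyte and 3 of 6 erythroid markers, and 5 of 9 interferon genes. Of 14 ovary and germ cell markers Fst rose by 1.94 ± 0.29, also over the list alone (camera adjusted p = 0.493). Fst encodes follistatin, which binds activin. Of 16 chondrocyte and osteoblast genes Sp7 fell by 0.98 ± 0.21, also over the list alone (camera adjusted p = 0.376), a call lost in 5 of the 6 fits that left out 1 array (adjusted p up to 0.135). No member passed, over all genes or adjusted over the list alone, in 8 further lists, except that 1 adipocyte gene and 1 neuron marker rose without control 3. Their camera adjusted p was 0.746 for 10 adipocyte genes, 6 erythroid markers and 11 Wolffian duct and kidney markers each, 0.0573 for 11 testis and steroidogenic markers, and 0.618 for 13 skeletal muscle markers. It was 0.281 for 10 neuron and Schwann cell markers, 0.224 for 9 interferon response genes and 0.589 for 3 Y-linked genes. The testis and steroidogenic list was called down without control 3 (0.0322), without mutant 1 (0.0180) and without rows under the 25th percentile of signal (0.0413). The neuron list was called down without control 2 (0.0462). Its mean deviation was 0.88 in control 3 and between -0.31 and -0.05 on the other 5 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty had group means between 2.50 and 3.48, below background.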

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

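The alternatives of this part were all planned, and only the counts of list medians were chosen after the result was seen. No called count, list or named gene changed direction under any of them. The median log2 fold change of all rows moved to -0.026 under quantile normalization and 0.008 with arrays shifted to a common median. Calls numbered 728 and 755 under these scalings, and 706 and 710 of the 723 main calls were kept. Signal over background limits the dim genes: 45 of the 2-fold changes had all control arrays below background and 10 all mutant arrays.

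Some counts moved by over 1.5 times. Falls numbered 257 without rows under the median signal, where 11103 rows were tested, and 243 with a trended and robust prior. At a threshold of 0.01 there were 299 calls, 260 up and 39 down. The plain unequal-spread test called 0, with 0 up and 0 down (smallest adjusted p 0.0960), while 1347 rows rose and 985 fell at an unadjusted p under 0.05. In limma 1885 rose and 1513 fell at that level. With 1 array left out, totals ranged from 360 to 697, rises from 305 to 565, falls from 55 to 132, 2-fold changes from 354 to 620 and 2-fold falls from 54 to 109. The lowest came without mutant 1 and the highest without control 3. Totals were 384 without control 1 and 454 without control 2, rises were 320 and 378, and falls were 64, 76 and, without mutant 3, 92. 2-fold falls were 63 without control 1. Of the 723 main calls, between 351 and 571 were kept. Fewer arrays were fitted in each of these.

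Lats1 stayed at -0.785 but passed the threshold without rows under the median signal (adjusted p = 0.0453) and with the trended and robust prior (0.0359). The Lats1 adjusted p ranged from 0.0359 to 0.286 over all alternatives.

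Under an estimated correlation 1 list was called up and 0 down. The adjusted p was then 0.127 for Hippo components, 0.343 for extracellular matrix and for Hox genes, 0.0893 for focal adhesion and for TGF-beta genes, 0.526 for proliferation, 0.101 for p53 targets and for hypoxia genes, 0.0667 for macrophage markers and 0.147 for immediate early genes. With fry, which does not set a list against other genes, 0 lists were called down (Hox 0.0647, proliferation 0.210). In the camera test proliferation was lost at 0.0677 and 0.0891 under the 25th percentile and median filters and at 0.0656 with array weights, and extracellular matrix at 0.159 under the median filter. Lists called down then numbered 1 under the median filter and 1 with array weights. With 1 array left out, the adjusted p ranged from 0.00864 to 0.0923 for extracellular matrix, 0.0109 to 0.246 for proliferation and 0.00388 to 0.0579 for Hox genes, and lists called down from 0 to 3. Apart from fewer rows or arrays, the cause was not tested. Of the 19 lists that were not called, 10 had a median that changed sign with 1 array left out and 16 a median that changed sign or moved by over 1.5 times, counts added after seeing the data.

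The control and mutant samples share replicate numbers, but these did not pair them: deviations of same-numbered arrays correlated at 0.008, 0.042 and -0.003. With a replicate block 633 transcript clusters were called, 578 of them among the 723, and 551 changed at least 2-fold. Under the block, extracellular matrix genes had an adjusted p of 0.0572 and proliferation genes of 0.0624.

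Of 144 named genes 74 passed the threshold. Of these 59 were kept in every fit without 1 array, 15 were lost in at least 1, and 8 were lost in another alternative. Of the 70 others, 13 passed in at least 1 alternative.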

Other observations

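The 6 gene lists below and the tests on macrophage markers, on Amhr2, on more smooth muscle in control 3 and on the neuron list in control 3 were chosen only after the result was seen, as were the member counts with 1 array left out, while the test of urinary tract tissue was set before the values of its 11 markers were seen. Genes of these lists are named after their values were seen.

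Several metabolic and cytokine lists were higher in mutant ducts with a preset correlation. Among 14 glycolysis enzymes 5 rose and none fell, or 12 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 0.90, and Hk2 rose by 1.69 ± 0.23 (SE) and Aldoa by 1.35 ± 0.24. A hypothesis that the rise covers the enzymes as a set had a camera adjusted p of 5.19e-08 (adjusted p = 0.183 with an estimated correlation), and the median of members that did not pass was 0.52. Pgk1, which rose, is also in the hypoxia list. With 1 array left out, 2 rose without control 2, 1 without mutant 1, 1 without mutant 2 and 3 without mutant 3. Among 15 cholesterol synthesis genes 4 rose, Cyp51, Fdps, Nsdhl and Hsd17b7, by between 1.22 and 1.68, or 10 adjusted over the list alone, with a list median of 0.95. Their mean deviation differed among controls, from -1.05 in control 2 to 0.14 in control 3. The count was 9 without control 3, 0 without control 1, mutant 1 or mutant 2, and 1 without control 2 or mutant 3. As a set they had a camera adjusted p of 1.90e-08 (adjusted p = 0.344 with an estimated correlation), and the median of members that did not pass was 0.73. The immediate early and stress list, fixed as a sign of sample quality, also differed between the genotypes. Its mean deviation was between -0.75 and -0.19 on control and between 0.52 and 0.59 on mutant arrays.

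Genes of interleukin-6 family signalling rose in 7 of 19 cases, or 9 adjusted over the list alone, and none fell. The receptor Osmr rose 14.7-fold, the ligand Lif by 2.15 ± 0.21, the transcription factor Stat3 by 2.19 ± 0.23 and Il6 by 1.72 ± 0.23, with Lif and Il6 below background in controls. The mean of Il6 in mutant ducts, 5.658, was also under the lowest background level of the mutant arrays, 5.671, so its rise is of little precision. The list's camera adjusted p was 4.52e-09 (adjusted p = 0.0534 with an estimated correlation). Osmr was already among the largest rises when the list was written, so this p partly restates its rise. The immediate early and stress list, fixed as a sign of sample quality and sharing Junb, moved with the interleukin-6 genes. Its mean deviation was between 0.52 and 0.59 on mutant arrays, beside 0.39 to 0.53 for the interleukin-6 list. Of 12 ligands that act on macrophages 2 rose, also over the list alone, Csf1 by 2.37 ± 0.19 and the chemokine Ccl12 by 3.68 ± 0.27, with a camera adjusted p of 0.0292 (adjusted p = 0.183 with an estimated correlation), a call also lost without control 2 (0.0906). Retnlg, Stfa2 and Stfa2l1, already among the largest falls when the list was written, fell among 16 neutrophil markers, or 4 adjusted over the list alone. The median of these neutrophil markers was -0.50 (camera adjusted p = 0.000198; adjusted p = 0.442 with an estimated correlation). On the array of control 2, the mean deviation of these markers was 1.45, against values between -0.56 and 0.02 on the other 5, and the adjusted p of the list was 0.0223 without control 2 and 0.0715 without rows under the median signal. The median was -0.22 without control 2, where 3 fell and 1 rose, and -0.78 without control 3, and 1 fell without control 1 and without each mutant array. Of 10 mast cell markers, Ms4a2 rose, at a signal below background, and Cpa3 fell, or 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.116). Without mutant 1, 2 fell and none rose (0.0325).

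Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many as 723 calls and 1 as many as 548 calls of at least 2-fold, the split by genotype in both cases, and the highest of the others gave 0. The splits are too few for a share under 0.05. The 5222 negative-control rows had a mean median of 7.32 ± 0.10 (SD, n = 3) in control and 7.11 ± 0.02 in mutant arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Control 3, whose negative-control rows lay nearer the mutant level, was shifted toward the mutants by 0.055 of the mutant shift (95% interval over rows 0.026 to 0.091). This was over the 746 rows with a log2 fold change of at least 1 in size, called or not. Control 3 is itself part of that fold change, so rows where it lay near the mutants were less often chosen. The interval holds no spread between embryos. The share therefore does not decide whether that lower level is the source of differences of that size.

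Control 3 stood apart from the other arrays in urothelial, smooth muscle and neuronal transcripts, with a median excess of 5.32 over the other 5 arrays in 9 urothelial markers that were picked because they were high in it and so exclude nothing. A candidate explanation is urinary tract tissue in the sample, which was put to 11 urothelial markers whose values had not been seen, 2 of them above background on all of the other 5 arrays. Their median excess was 0.38 (95% interval 0.06 to 1.69), with 5 highest in control 3, which missed the size of over 1 set before the test and leaves it open. More smooth muscle within the duct and no other tissue was not decided by these markers either, nor by the neuron and Schwann cell list, with a median excess of 0.99 (95% interval 0.40 to 1.61) against a bound of 0.5. The labels name no difference between the control embryos, and without control 3 571 of the 723 main calls were kept and 0 reversed.

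Macrophage markers rose by a mean of 1.13. A lower share of the main cells would raise markers of every other cell type alike, but 43 endothelial, epithelial and mesothelial markers had a mean of -0.02, a difference of -1.15 (two-sided permutation p = 1e-05, the smallest the resamples can give, over genes that are not independent). These lists were set against each other after their changes were known, so this p-value is no independent support. Without control 3 the mean of the 43 markers was 0.11 and the difference -1.01. More leukocytes of every kind would raise neutrophil and mast cell markers too. The 26 measured had a mean of -0.60, a difference of -1.73 (permutation p = 1e-05, again the smallest). Control 2 carried much of that mean, which was -0.26 without it, with a difference from macrophage markers of -1.37 (permutation p = 4e-05). Retnlg, Stfa2 and Stfa2l1, already seen among the largest falls, were put in the neutrophil list, so these p-values are no independent support. The 13 neutrophil markers without a call had a median of -0.41, with Camp, Ltf and Stfa1 below background in group means. The list set against them held macrophage and leukocyte markers, so more leukocytes of every kind was not decided. More macrophages in mutant ducts, or a higher level of these transcripts per macrophage, may account for the rise, and the arrays cannot separate them.

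Amhr2 fell by far more than other mesenchyme genes. Loss of 1 of 2 alleles to Cre, and nothing else, would give a log2 fold change of about -1, and the upper end of the 95% interval was -3.17. A smaller share of mesenchyme is argued against by the other 12 mesenchyme genes, whose median was -0.06 with a bootstrap interval from -0.31 to 0.09. No other explanation was tested.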
